A study of Mus musculus with 23 samples.

How the data were processed

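Poly-A RNA from the hippocampi of 23 mice, aged about 5 months, was sequenced with 1 library per mouse. The genotypes were wild type (WT, n = 6), loss of p16 (p16KO, n = 6), the App knock-in (AppNLGF, n = 5) and both together (AppNLGF_p16KO, n = 6). Stranded libraries were made from 350 ng of total RNA with 12 PCR cycles and read as 50-base single ends on a NextSeq 2000, per the labels' protocols. Reads were trimmed with cutadapt 4.2 at a Phred score of 20, and those shorter than 40 bases were dropped, per the submitters' processing notes. Ribosomal reads were removed with Bowtie2 2.3.5 and the remainder aligned with STAR 2.7.10b to the GRCm38 genome, per the submitters' processing notes. The deposited values are raw counts: the authors counted the reads that aligned uniquely and fell unambiguously in 1 gene of Ensembl release 102, per the labels and the processing notes. No normalisation had been applied to these counts, which were whole numbers with a different total in every library. The submitters used DESeq2 1.45.3 in their own work, per the labels, and that output was not used here. The labels also list a later mouse build. Of the 37060 genes shared with a GRCm38 annotation (GENCODE M21), 36795 had identical coordinates, so GRCm38 positions are given.

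The table held 37173 genes, and all its columns were used. Total counts ran from 40.7e6 to 61.2e6 per library (median 55.1e6). The libraries carried no molecular identifiers, so PCR copies of a molecule were not separated and statements on depth cover counting error only. The submitters' notes state that 18768 genes passed their filter. Asking for 15 reads or more in at least 3 of 23 libraries, over 10% of them, returned 18768 genes. The same minimum in 90% of the libraries kept 16205. The edgeR function filterByExpr with the 4 groups and a minimum of 10 kept 19423 genes, which were the genes tested.

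Gene tests used edgeR 4.0.16 in R 4.3.3 (TMM normalisation, quasi-likelihood F test, robust dispersion, 1 model for the 4 genotypes and all 23 libraries), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The common dispersion was 0.0249, a biological coefficient of variation of 15.8%. The contrasts were p16KO minus WT, AppNLGF minus WT, AppNLGF_p16KO minus AppNLGF, AppNLGF_p16KO minus p16KO, AppNLGF_p16KO minus WT, their interaction, and the average p16 and App effects over both backgrounds. Adjusted p-values of genes come from this test unless another tool is named. Group values are counts per 1e6 counts (CPM), as mean ± SD, and log2 fold changes are given ± SE. The number of libraries in a direction counts those of the first-named group on the stated side of the other group's mean. Cdkn2a had too few reads for this test and was compared with a two-sided exact permutation test on CPM.

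Lists of genes, 42 in all, for cell types, hippocampal subfields, neighbouring regions and pathways were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 42 lists. The same test was repeated with a correlation estimated from the data. Calls near Cdkn2a and App were compared with calls elsewhere among the genes tested by Fisher's exact test, two-sided, in a window of 10 Mb on either side.

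The comparisons, tests, lists and rules for naming genes were fixed before the data were examined. The rule named, in each of the 4 contrasts between neighbouring genotypes, the 6 rising and 6 falling genes with the smallest p past the threshold, leaving out predicted genes. It added up to 4 members of each list described, or 1 to 2 of the most abundant where none passed, and always Cdkn2a, Cdkn2b, Mtap and App. For the other contrasts it named the 5 genes with the smallest p, or 2 where none passed. Where fewer than 15 genes were called, all those with a symbol were named. Some genes named by this rule are not reported here.

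The procedure was tested on simulated data for p16KO minus WT, with 19423 genes of which 200 were changed, 50 at each fold, besides the genes of a complement list changed 1.5-fold. edgeR recovered 20% of changes of 1.2-fold, 50% of 1.5-fold, 70% of 2-fold and 92% of 4-fold, and 4 of its 129 calls were unchanged genes. DESeq2 1.42.0 recovered 24%, 60%, 74% and 92%, with 18 unchanged genes among 152 calls. That complement list was found by camera (adjusted p = 1.41e-28) and 0 of the other lists were called. Genes were simulated independently of each other, so this does not test how often the preset correlation calls lists of genes that vary together.

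Alternatives were DESeq2 1.42.0 (Wald test), RLE size factors, 2 other count filters and none, a fit without robust dispersion, fits of the compared groups alone, 1 surrogate variable from sva 3.50.0, a sex score, omission of each library in turn, omission of libraries past the submitters' distance limit, and omission of genes near Cdkn2a and App. Stricter thresholds and other windows were also tried. Added after the data were examined were the filter that returned 18768 genes, the omission of AppNLGF_p16KO libraries 21 and 22 together, removal of a trend of counts on transcript length and GC content (a spline with 5 degrees of freedom, with a value for 99.93% of the genes tested), and the omission of the chromosome of Cdkn2a. For loss of p16 as the cause of the calls on chromosome 4, the bound asked for was first that of the chromosome, then that within 10 Mb, and last that of the chromosome at a level corrected for the choice of 1 among 22. Each of these was set after the values were seen, and only the 10 Mb bound left that cause open. Sex was read from Xist and Y-linked genes. Batch could not be modelled, since the labels give none.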

Results

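Messenger RNA of the hippocampus was counted in 23 mice of about 5 months in a design with 2 factors. They were loss of p16, the product of Cdkn2a that inhibits the cyclin D kinases, and the App knock-in AppNLGF. The App gene of the knock-in carries familial Alzheimer mutations. There were 6 WT, 6 p16KO, 5 AppNLGF and 6 AppNLGF_p16KO libraries. Total counts were 54.6e6 to 58.7e6 in WT, 45.4e6 to 61.2e6 in p16KO, 40.7e6 to 57.0e6 in AppNLGF and 48.6e6 to 59.5e6 in AppNLGF_p16KO. The mitochondrial share of counts ran from 2.79% to 3.99%. Markers split each group nearly evenly by sex, with Xist in 3 of 6, 3 of 6, 2 of 5 and 3 of 6 libraries. Of 37173 genes, 19423 were tested.

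Cdkn2a, the gene named by the p16KO label, lies on chromosome 4 (ENSMUSG00000044303, GRCm38 89274471 to 89294653) and was near the floor of detection in every library. WT libraries 1 to 6 held 6, 1, 3, 0, 5 and 2 reads, and p16KO libraries 7 to 12 held 0, 1, 2, 1, 0 and 0. AppNLGF libraries 13 to 17 held 2, 6, 9, 4 and 4 reads, and AppNLGF_p16KO libraries 18 to 23 held 0, 6, 6, 2, 8 and 2. The mean was 0.0504 CPM in WT (17 reads), 0.0117 in p16KO (4 reads), 0.0946 in AppNLGF (25 reads) and 0.0769 in AppNLGF_p16KO (24 reads). In exact permutation tests p was 0.0649 for p16KO against WT (924 splits) and 0.595 for AppNLGF_p16KO against AppNLGF (462 splits). AppNLGF_p16KO held more reads than p16KO (p = 0.0303, exact permutation test, 924 splits). By the same exact permutation test p was 0.123 for AppNLGF against WT (462 splits) and 0.372 for AppNLGF_p16KO against WT (924 splits). A loss of reads was therefore not shown at 0.05 in either group labelled as lacking p16, although p16KO held fewer reads than WT. The excess of AppNLGF_p16KO over p16KO does not test its label, since both groups are labelled as lacking p16. These exact tests were not adjusted for their number. Counts per gene do not separate the p16INK4a and p19ARF transcripts that share Cdkn2a, and the labels do not describe the deleted part. Directions below that involve p16 refer to the libraries labelled p16KO and AppNLGF_p16KO, not to a measured loss of the transcript.

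**Figure D1:**
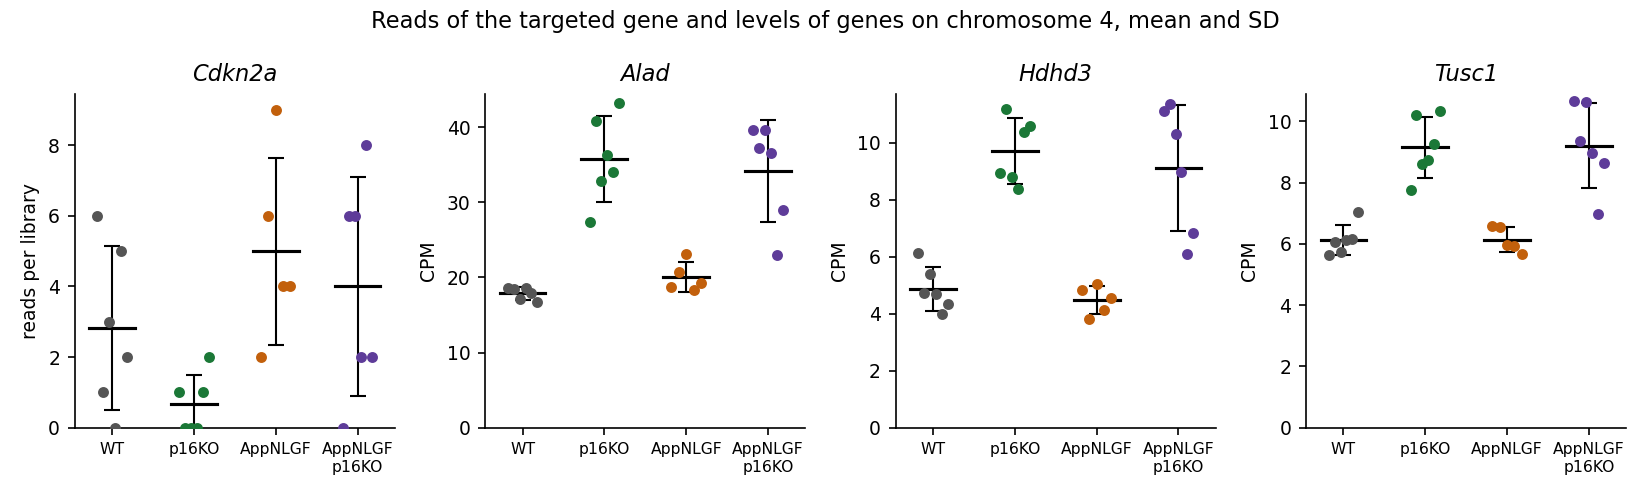
Reads of Cdkn2a and CPM of Alad, Hdhd3 and Tusc1 in each library, by genotype, with the group mean and SD as bars. Alad averaged 17.9 CPM in WT and 35.8 CPM in p16KO, while the library labelled AppNLGF_p16KO 22 stood at 22.9 CPM.

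The first comparison asked what loss of p16 changes where App is wild type. Alad, which encodes the haem synthesis enzyme aminolevulinate dehydratase (ENSMUSG00000028393, chromosome 4, 62509169 to 62519918), rose from 17.9 ± 0.814 to 35.8 ± 5.70 CPM (log2 1.00 ± 0.11, adjusted p = 1.09e-04, higher in 6 of 6 libraries labelled p16KO). Its neighbour Hdhd3, a predicted hydrolase gene (62499008 to 62503467), rose from 4.89 ± 0.771 to 9.72 ± 1.15 CPM (log2 0.99 ± 0.14, adjusted p = 8.38e-04, 6 of 6). Tusc1, a candidate tumour suppressor gene at 93334138 to 93335511 on the same chromosome, rose from 6.13 ± 0.5 to 9.16 ± 0.998 CPM (log2 0.58 ± 0.09, adjusted p = 0.00762, 6 of 6). Cyp2j13, a cytochrome P450 gene of chromosome 4, was scarce and rose from 0.0567 ± 0.0146 to 0.398 ± 0.216 CPM (log2 2.78 ± 0.46, adjusted p = 0.00920, 6 of 6). Smox, the spermine oxidase gene of chromosome 2, rose by log2 0.39 ± 0.07 to 50.8 ± 1.80 CPM (adjusted p = 0.0138, 6 of 6).

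Rab3b, a synaptic vesicle GTPase gene, fell from 57.4 ± 4.35 to 36.0 ± 6.27 CPM (log2 -0.68 ± 0.12, adjusted p = 0.0166, lower in 6 of 6). Frrs1l, whose product assembles AMPA receptors, fell from 549.5 ± 22.1 to 409 ± 51.0 CPM (log2 -0.43 ± 0.08, adjusted p = 0.0166, 6 of 6). Phf24, a regulator of GABA-B signalling, fell from 244 ± 17.8 to 180.3 ± 15.7 CPM (log2 -0.44 ± 0.09, adjusted p = 0.0242, 6 of 6). These 3 genes lie on chromosome 4. Zfp110 fell by 0.35 on the log2 scale (SE 0.07, adjusted p = 0.0372), the non-coding Mccc1os by 0.50 (SE 0.11, adjusted p = 0.0421) and the orphan receptor gene Gpr26 by 0.30 (SE 0.07, adjusted p = 0.0430), each lower in 6 of 6. In all, 60 of 19423 genes passed, 51 up and 9 down, with a median absolute log2 change of 0.40. An unadjusted p under 0.05 was found for 3071. Among those with the smallest p were the predicted gene Gm13453 (log2 4.51 ± 0.58, adjusted p = 5.89e-04) and Gm20075 (log2 2.92 ± 0.41, adjusted p = 9.27e-04), both chosen after their values were seen. The count was carried by single libraries. It was 7 without p16KO 9, 10 without p16KO 11, 12 without WT 2 or WT 4 and 14 without WT 3. It was 18 without WT 6, 19 without WT 5 or p16KO 12, 136 without WT 1 and 238 without p16KO 8. DESeq2 called 469 genes. A fit of both groups alone called 307, and a fit with length and GC trends removed 32. Alad, Hdhd3, Tusc1 and Cyp2j13 passed in all 12 fits without 1 library, and Tusc1 had adjusted p = 0.0784 with length and GC trends removed (6.93e-06 to 0.0784 over its alternatives). The call of Smox ended without p16KO 9 (adjusted p = 0.0581), and that of Rab3b without p16KO 9 (0.0668) or 11 (0.0519). Frrs1l was lost without WT 2 (0.0517), p16KO 9 (0.0695) or 11 (0.0519). Removing length and GC trends gave Frrs1l 0.107. Phf24 was lost without WT 2, 3, 4 or 5 or p16KO 9 or 11 (up to 0.0856). Zfp110 was lost without any library except WT 1 and p16KO 8 and 10 (up to 0.116), and Mccc1os except WT 1 and p16KO 8 (up to 0.141). Gpr26 was lost for all except p16KO 8 (up to 0.138, and 0.354 with length and GC trends removed).

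Position on chromosome 4 set these calls apart. Within 10 Mb of Cdkn2a, 2 of 70 genes tested were called (odds ratio 9.78, 95% interval 1.13 to 38.3, Fisher's exact p = 0.0198). A window of 5 Mb gave 1 of 27 and an odds ratio of 12.6 (Fisher's exact p = 0.0802). On the whole chromosome, a region chosen after the calls were seen, 18 of 1110 genes were called (odds ratio 7.17, 3.87 to 12.8, Fisher's exact p = 3.46e-09). They lay from 41.6 to 139.3 Mb, among them Alad, Hdhd3, Tusc1, Cyp2j13, Rab3b, Frrs1l, Phf24 and Nans. By number of calls chromosome 7 was next, with 7 of 1529, and by share of the genes tested chromosome 17, with 5 of 914. The direct neighbours of Cdkn2a did not pass. The inhibitor gene Cdkn2b changed by log2 0.63 ± 0.23 (adjusted p = 0.179, 0.537 to 0.829 CPM, higher in 5 of 6). Mtap, of methionine salvage, changed by log2 -0.32 ± 0.09 (adjusted p = 0.0871, lower in 6 of 6). Mtap passed with DESeq2 (adjusted p = 0.0240), with both groups alone (0.0357), without AppNLGF_p16KO 21 (0.0459) and without AppNLGF_p16KO 21 and 22 (0.0320). The range was 0.0240 to 0.198. App itself was at log2 -0.04 ± 0.04 (adjusted p = 0.653).

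**Figure D2:**
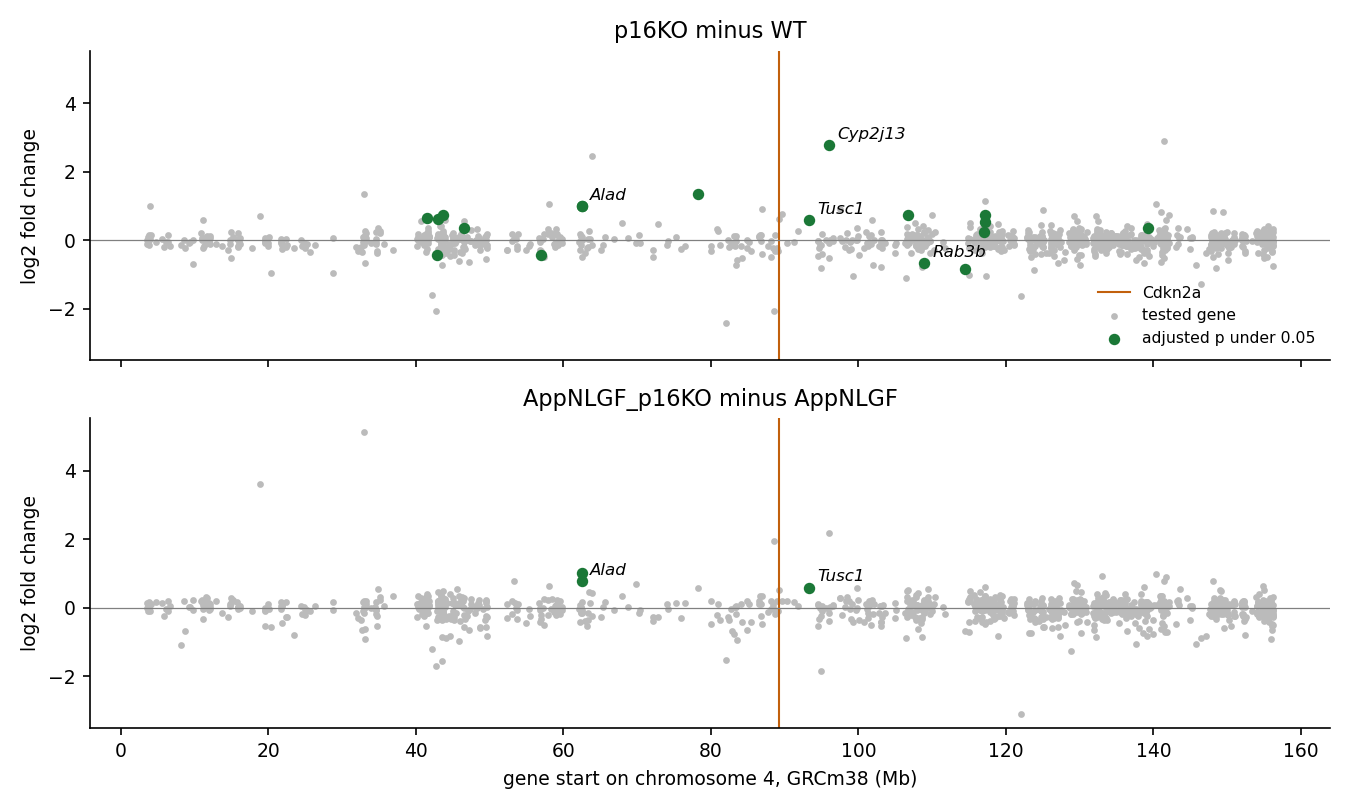
Log2 fold change of each gene tested along chromosome 4 (position in Mb, GRCm38) for p16KO minus WT and for AppNLGF_p16KO minus AppNLGF, with genes at an adjusted p under 0.05 in green and Cdkn2a as an orange line. The 18 calls of p16KO minus WT spread from 41.6 to 139.3 Mb.

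Among gene lists, those of the respiratory chain and the ribosome were higher in libraries labelled p16KO. The 48 nuclear genes of oxidative phosphorylation had a median log2 change of 0.15 with 44 positive (camera adjusted p = 1.15e-13, adjusted p = 0.729 with an estimated correlation). Uqcrq, a complex III subunit gene, was the 1 member called (log2 0.39 ± 0.08, 89.2 ± 4.43 to 117 ± 13.2 CPM, adjusted p = 0.0433, 6 of 6). When adjusted over the list alone, 22 passed. Of 76 cytosolic ribosomal protein genes 6 were called and 29 adjusted over the list alone (median log2 0.17, 65 positive, camera adjusted p = 1.18e-13, adjusted p = 0.729 with an estimated correlation). Among them were Rplp1 (log2 0.50 ± 0.10, adjusted p = 0.0258), Rps21 (log2 0.50 ± 0.11, adjusted p = 0.0407) and Rplp2 (log2 0.26 ± 0.06, adjusted p = 0.0407), each higher in 6 of 6. The type I interferon response, 31 genes of antiviral defence, was lower (median log2 -0.31, 3 positive, camera adjusted p = 1.66e-05, adjusted p = 0.729 with an estimated correlation). edgeR called 0 members over all genes, and 2 were down adjusted over the list alone. Stat2, an abundant member, did not pass (log2 -0.17 ± 0.09, adjusted p = 0.352, lower in 6 of 6). Extracellular matrix genes were lower (26 genes, median log2 -0.16, camera adjusted p = 0.00107, 0 called and 1 down adjusted over the list alone), Sparcl1 being at log2 -0.14 ± 0.06 (adjusted p = 0.284). Targets of p53 were higher (24 genes, median log2 0.12, 19 positive, camera adjusted p = 0.0122), with 0 called over all genes or over the list alone. Markers of other tissue were lower beside the matrix genes. Meninges and fibroblast genes had a median log2 of -0.25 (20 genes, camera adjusted p = 0.0280) and neocortex genes of -0.15 (18 genes, camera adjusted p = 0.0184), with 0 called by edgeR over all genes or over either list alone. The meninges call ended without WT 3 (0.0923), 4 (0.0551) or 6 (0.118) or p16KO 7 (0.202), 10 (0.109) or 12 (0.0792), and its median was -0.38 without p16KO 9. The neocortex call ended without WT 1 (0.103) or p16KO 10 (0.0636). With an estimated correlation these 4 lists had adjusted p = 0.729, and 0 of the 10 list calls of this contrast held. The lists closest to p16 were not called. The cyclin-dependent kinase and Rb family had a median log2 of 0.01 (adjusted p = 0.324), E2F targets 0.02 (adjusted p = 0.906) and the senescence and secretory phenotype 0.05 (adjusted p = 0.380). edgeR called 0 members of each over all genes and over the list alone. Disease-associated microglia genes were at 0.07 (adjusted p = 0.0991). The call of Uqcrq ended without any library except WT 1 and p16KO 7 and 8 (adjusted p up to 0.154). Those of Rplp1 and Rplp2 ended for all except WT 1 and p16KO 7, 8 and 10 (up to 0.142), and that of Rps21 except WT 1 and p16KO 7 and 8 (up to 0.128). Removing length and GC trends gave Uqcrq 0.0692 and Rplp2 0.0806.

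The second comparison asked what the App knock-in changes where p16 is present, and its largest changes were in microglial genes. RNA came from hippocampal tissue, so here and below more microglia cannot be told apart from higher levels per cell. Cst7, encoding cystatin F, a protease inhibitor induced in microglia around plaques (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), rose from 0.178 ± 0.106 to 5.93 ± 1.57 CPM (32.9-fold, log2 5.04 ± 0.33, adjusted p = 2.30e-09, higher in 5 of 5). The dectin-1 gene Clec7a rose from 0.525 ± 0.161 to 3.76 ± 0.925 CPM (log2 2.83 ± 0.24, adjusted p = 9.21e-08, 5 of 5). The integrin gene Itgax, a marker of the same state, rose from 0.371 ± 0.143 to 2.68 ± 0.738 CPM (log2 2.84 ± 0.25, adjusted p = 9.21e-08, 5 of 5). The lipid receptor gene Trem2 and its adaptor Tyrobp rose together. Trem2 reached 22.8 ± 2.05 from 11.3 ± 1.19 CPM (log2 1.01 ± 0.09, adjusted p = 9.21e-08, 5 of 5). Tyrobp reached 24.4 ± 2.83 from 12.1 ± 1.04 CPM (log2 1.01 ± 0.09, adjusted p = 9.21e-08, 5 of 5). The chemokine gene Ccl6 rose from 1.85 ± 0.476 to 6.60 ± 0.642 CPM (log2 1.84 ± 0.16, adjusted p = 9.21e-08, 5 of 5). The 3 falling genes included Stmn4, of neuronal microtubules (log2 -0.32 ± 0.07, adjusted p = 0.0258, 185 to 149 CPM). The others were the activity-dependent genes Egr2 (log2 -0.98 ± 0.21, adjusted p = 0.0328, 3.88 to 1.96 CPM) and Sik1 (log2 -0.45 ± 0.10, adjusted p = 0.0366, 14.8 to 10.8 CPM), each lower in 5 of 5. Altogether 62 genes passed, 59 up and 3 down (1658 with an unadjusted p under 0.05), and DESeq2 called 153. The 6 microglial genes passed in all 11 fits without 1 library. The call of Stmn4 ended without WT 1 or 4 or AppNLGF 13, 15 or 16 (adjusted p up to 0.108). That of Egr2 ended without any library except WT 3 and 4 and AppNLGF 14 (up to 0.115), and that of Sik1 except WT 3 and AppNLGF 13 and 16 (up to 0.140). App was at log2 -0.10 ± 0.05 (adjusted p = 0.572, lower in 5 of 5), Cdkn2b at 0.43 ± 0.24 (adjusted p = 0.657) and Mtap at -0.01 ± 0.09 (adjusted p = 0.995). Within 10 Mb of App, 1 of 96 genes was called (odds ratio 3.32, Fisher's exact p = 0.265).

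Disease-associated microglia genes were higher (36 genes, median log2 0.61, 32 positive, camera adjusted p = 2.68e-40, adjusted p = 3.73e-05 with an estimated correlation). Of its members 14 were called, and 20 adjusted over the list alone. Homeostatic microglia genes were higher as well (23 genes, median log2 0.24, 22 positive, camera adjusted p = 2.12e-15, adjusted p = 4.89e-04 with an estimated correlation, 3 called and 13 adjusted over the list alone). The fatty acid receptor gene Gpr84 rose by log2 1.29 ± 0.19 (adjusted p = 4.93e-04, 5 of 5) and Olfml3 by log2 0.46 ± 0.10 (adjusted p = 0.0321, 5 of 5). Complement genes rose (18 genes, median log2 0.29, camera adjusted p = 2.14e-11, adjusted p = 0.00803 with an estimated correlation, 6 called and 7 adjusted over the list alone). Calls included C1qa (43.1 ± 3.72 to 65.0 ± 7.13 CPM, log2 0.59 ± 0.09, adjusted p = 5.04e-04), C4b (log2 0.75 ± 0.12, adjusted p = 0.00143), C3ar1 (log2 0.94 ± 0.15, adjusted p = 0.00145) and C1qc (log2 0.62 ± 0.10, adjusted p = 0.00207), each higher in 5 of 5. Without AppNLGF 16 the complement median was 0.14. Immediate early genes, which follow neuronal firing, fell (27 genes, median log2 -0.27, 1 positive, camera adjusted p = 1.41e-15, adjusted p = 0.00398 with an estimated correlation, 2 called and 11 adjusted over the list alone). Egr2 and Sik1 were those called. These 4 list calls held with an estimated correlation, and the other 13 of 17 did not. Among those 13 was the circadian clock list, which was lower. Its call ended without WT 1 (camera adjusted p = 0.0801), WT 4 (0.0583), AppNLGF 14 (0.1715) or AppNLGF 17 (0.0635). Library numbers ran by genotype, so an effect of the knock-in on these lists cannot be told apart from handling order. Lysosomal genes were higher (27 genes, median log2 0.12, camera adjusted p = 4.15e-11, adjusted p = 0.0913 with an estimated correlation, 4 called and 11 adjusted over the list alone). Calls were the proteases Ctsd (log2 0.55 ± 0.09, adjusted p = 0.00134) and Ctss (log2 0.51 ± 0.09, adjusted p = 0.00207) and the glucuronidase Gusb (log2 0.31 ± 0.06, adjusted p = 0.0178) among others, each in 5 of 5. In the astrocyte filament gene Gfap the rise was from 337 ± 33.2 to 479 ± 16.7 CPM (log2 0.51 ± 0.09, adjusted p = 0.00460, 5 of 5). It was the 1 call in the reactive astrocyte list over all genes and over the list alone (28 genes, median log2 0.06, camera adjusted p = 0.0438, adjusted p = 0.409 with an estimated correlation). That list call ended without WT 1, 2, 4 or 5 or AppNLGF 14 or 16 (adjusted p up to 0.182). It also ended with 15 reads in 90% of libraries (0.241), with no count filter (0.0749), without AppNLGF_p16KO 21 (0.0516) and without AppNLGF_p16KO 21 and 22 (0.0605). Its median was 0.11 without WT 3, 0.09 without WT 6 or AppNLGF 15 and 0.12 without AppNLGF 17.

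Interferon genes were higher with the App knock-in (31 genes, median log2 0.45, 30 positive, camera adjusted p = 2.17e-10, adjusted p = 0.320 with an estimated correlation). So were those of antigen presentation (19 genes, median log2 0.25, camera adjusted p = 1.08e-07, adjusted p = 0.0913 with an estimated correlation). Without AppNLGF 17 the interferon median was 0.18, and the list mean of that library was 2.26 against 1.03 to 1.43 in the others of its group. edgeR called 0 members of either over all genes, and 3 and 7 adjusted over the list alone. Neither Stat2 (log2 0.09 ± 0.09, adjusted p = 0.844) nor the light chain gene B2m of class I molecules passed (log2 0.43 ± 0.12, adjusted p = 0.165, and 0.0439 with DESeq2 in a range of 0.0439 to 0.390). Alzheimer risk genes were slightly higher (35 genes, median log2 0.07, camera adjusted p = 0.00103, adjusted p = 0.0747 with an estimated correlation, 2 called and 6 adjusted over the list alone). The called members were Trem2 and Cd33 (log2 0.38 ± 0.08, adjusted p = 0.0263, 5 of 5). The senescence and secretory phenotype list was at a median of 0.03 (adjusted p = 0.0575, 0 called by edgeR and 2 adjusted over the list alone). Amyloid processing genes were at -0.05 (adjusted p = 0.0647, 0 called by edgeR over all genes or over the list alone). Leaving out 1 library ended the call of Gusb for WT 1, 2 or 5 or AppNLGF 14 or 15 (adjusted p up to 0.0864). It ended that of Cd33 for WT 2, 4, 5 or 6 or AppNLGF 14 or 17 (up to 0.121) and of Olfml3 for any except WT 3 and 6 and AppNLGF 16 (up to 0.109). Gpr84, the complement genes, Ctsd, Ctss and Gfap passed in all 11 such fits.

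**Figure D3:**
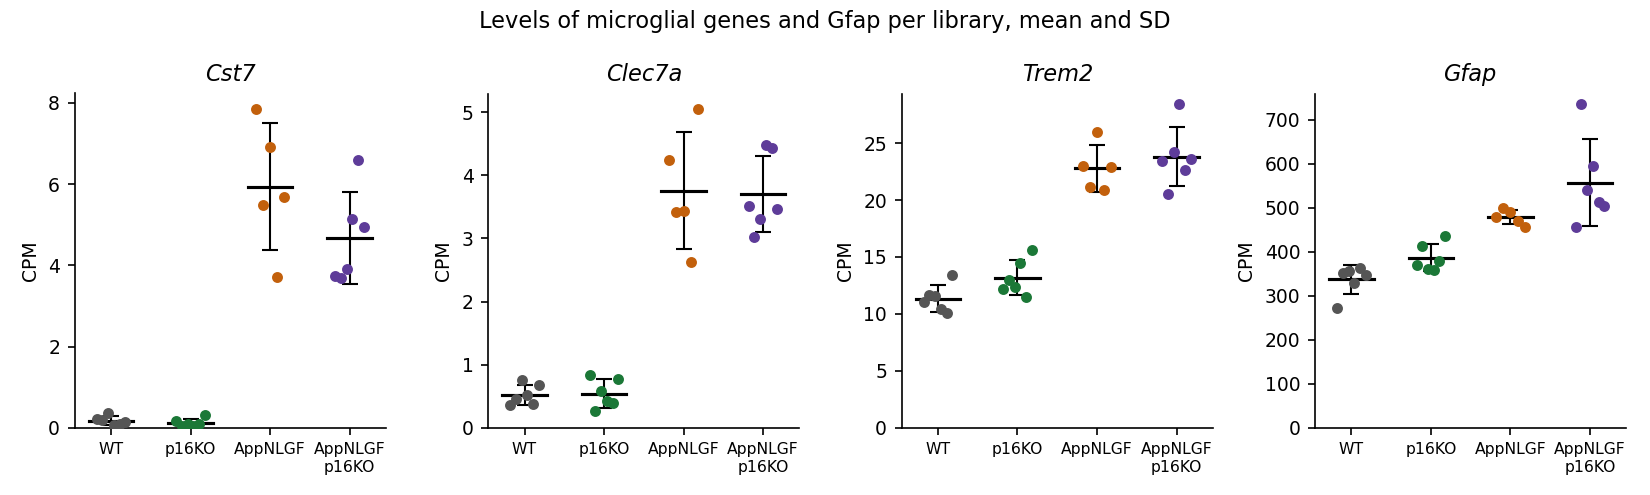
CPM of Cst7, Clec7a, Trem2 and Gfap in each library, by genotype, with the group mean and SD as bars. Cst7 averaged 0.178 CPM in WT, 0.130 in p16KO, 5.93 in AppNLGF and 4.67 in AppNLGF_p16KO.

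The third comparison asked what loss of p16 changes in the presence of the App knock-in. A loss of Cdkn2a reads was not shown in the libraries labelled AppNLGF_p16KO, nor in those labelled p16KO. The same chromosome 4 genes led. Hdhd3 rose from 4.49 ± 0.503 to 9.12 ± 2.23 CPM (log2 1.02 ± 0.15, adjusted p = 0.00427, 6 of 6). Alad rose from 20.0 ± 1.98 to 34.2 ± 6.74 CPM (log2 0.77 ± 0.12, adjusted p = 0.00771, 6 of 6, with overlapping groups), and Tusc1 from 6.14 ± 0.405 to 9.21 ± 1.39 CPM (log2 0.58 ± 0.10, adjusted p = 0.0160, 6 of 6). Cd2ap, an Alzheimer risk gene for an adaptor of the actin cytoskeleton on chromosome 17, fell from 31.4 ± 1.5 to 23.4 ± 3.28 CPM (log2 -0.43 ± 0.08, adjusted p = 0.0474, lower in 6 of 6). With the predicted genes Gm20075 (log2 3.14 ± 0.46, adjusted p = 0.00427) and Gm13453 (log2 3.47 ± 0.59, adjusted p = 0.0160), chosen after their values were seen, these were the 6 calls (5 up, 1 down). In all, 4570 genes had an unadjusted p under 0.05. The count was 2 without AppNLGF 16, 3 without AppNLGF 15 or AppNLGF_p16KO 18 or 20, 21 without AppNLGF_p16KO 22 and 4150 without AppNLGF_p16KO 23. DESeq2 called 676 genes, 2 of them shared, and edgeR with both groups alone called 0. There Hdhd3, Alad, Tusc1 and Cd2ap all had adjusted p = 0.270, the highest of their alternatives (lowest 8.98e-05, 3.38e-06, 7.17e-04 and 9.98e-04). The call of Alad ended without AppNLGF 16 (0.0574). That of Tusc1 ended without AppNLGF 15, 16 or 17 or AppNLGF_p16KO 18 or 20 (up to 0.0979) and with length and GC trends removed (0.0590). That of Cd2ap ended without any AppNLGF library or AppNLGF_p16KO 18 or 20 (up to 0.185). Within 10 Mb of Cdkn2a, 1 of 70 genes was called (odds ratio 55.9, 1.17 to 506, Fisher's exact p = 0.0214), and with DESeq2 the odds ratio was 1.24 (Fisher's exact p = 0.737). Cdkn2b was at log2 0.52 ± 0.24 (adjusted p = 0.186), Mtap at -0.11 ± 0.09 (adjusted p = 0.481) and App at -0.01 ± 0.04 (adjusted p = 0.922).

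The lists of the respiratory chain, the ribosome and the interferon response had the direction they had without the knock-in, while cholesterol synthesis genes had been at a median of -0.00378 there. Oxidative phosphorylation genes were higher in all 48 cases (median log2 0.24, camera adjusted p = 1.17e-20, adjusted p = 0.660 with an estimated correlation, 40 adjusted over the list alone). Cytosolic ribosomal protein genes were higher in 67 of 76 (median log2 0.15, camera adjusted p = 7.76e-07, adjusted p = 0.660 with an estimated correlation, 0 adjusted over the list alone). Interferon genes were lower in 30 of 31 (median log2 -0.65, camera adjusted p = 6.48e-10, adjusted p = 0.660 with an estimated correlation, 20 down adjusted over the list alone). Without AppNLGF 17 the interferon median was -0.34. Dentate gyrus genes were lower (19 genes, median log2 -0.14, camera adjusted p = 0.00186, adjusted p = 0.660 with an estimated correlation, -0.09 without AppNLGF_p16KO 21). Across 14721 genes, which are not independent replicates, the contrast correlated at 0.46 with the main axis of differences among libraries of the same genotype, on which AppNLGF_p16KO 23 (-31.3) and WT 1 (22.0) and AppNLGF_p16KO 21 (21.8) lay at the ends. That axis mostly followed sex, with 11 of 11 Xist libraries below 0 and 11 of 12 others above. With sex removed the main axis correlated at 0.544, and with the sex score in the model the same 6 genes were called. Cholesterol synthesis genes were higher (22 genes, median log2 0.26, camera adjusted p = 7.76e-07, adjusted p = 0.660 with an estimated correlation, 16 adjusted over the list alone). edgeR called 0 members of these 5 lists over all genes, and 0 of the dentate gyrus list adjusted over the list alone. Among the abundant members of the others, which did not pass, were the ATP synthase genes Atp5b and Atp5a1 (both log2 0.24 ± 0.07, adjusted p = 0.112), Rpl4 (log2 0.15 ± 0.05, adjusted p = 0.131), Rps3 (log2 0.24 ± 0.07, adjusted p = 0.112), Stat2 (log2 -0.23 ± 0.09, adjusted p = 0.151) and Hmgcs1 (log2 0.27 ± 0.13, adjusted p = 0.196). Without AppNLGF_p16KO 23 all 6 passed (adjusted p = 0.00496, 0.00499, 0.0193, 0.00573, 0.0140 and 0.0415). The 7 mitochondrially encoded genes were lower (median log2 -0.15, camera adjusted p = 0.0171, adjusted p = 0.660 with an estimated correlation, 0 called by edgeR and 3 adjusted over the list alone), a call that ended without AppNLGF 14 (0.0555). With an estimated correlation 0 of the 9 list calls held. Disease-associated microglia genes were not called (median log2 0.04, mean -0.04, adjusted p = 0.883, 0 called by edgeR over all genes or over the list alone). Nor were the senescence and secretory phenotype (median 0.03, mean -0.00362, test direction up, adjusted p = 0.562), the cyclin-dependent kinase and Rb family (median 0.07, adjusted p = 0.491) or E2F targets (median 0.06, adjusted p = 0.690).

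The fourth comparison asked what the App knock-in changes when p16 is lost. Cst7 rose from 0.130 ± 0.0985 to 4.67 ± 1.13 CPM (34.7-fold, log2 5.12 ± 0.34, adjusted p = 2.82e-09, 6 of 6). Clec7a rose from 0.541 ± 0.226 to 3.71 ± 0.610 CPM (log2 2.77 ± 0.23, adjusted p = 8.83e-08, 6 of 6), and Itgax by log2 2.59 ± 0.25 (adjusted p = 4.35e-07, 6 of 6). The chemokine gene Ccl6 rose by log2 1.78 ± 0.16 (adjusted p = 1.55e-07), and the phagocyte glycoprotein gene Cd68 from 7.59 ± 0.536 to 14.8 ± 1.47 CPM (log2 0.97 ± 0.09, adjusted p = 1.55e-07). Tyrobp rose by log2 0.89 ± 0.08 (adjusted p = 4.35e-07) and Trem2 by log2 0.85 ± 0.09 (adjusted p = 9.12e-07), each in 6 of 6. Gfap rose from 387 ± 31.1 to 558 ± 99.1 CPM (log2 0.53 ± 0.09, adjusted p = 0.00304, 6 of 6). The 5 falling genes included Il1r1, of interleukin-1 signalling (log2 -0.65 ± 0.13, adjusted p = 0.0372), and Mns1, of motile cilia (log2 -0.83 ± 0.18, adjusted p = 0.0375), with 3 others. These were the histone demethylase gene Kdm7a (log2 -0.30 ± 0.06, adjusted p = 0.0375), the chaperone gene Dnajb5 (log2 -0.23 ± 0.05, adjusted p = 0.0375) and the ubiquitin ligase gene Rnf19a (log2 -0.27 ± 0.06, adjusted p = 0.0461), each lower in 6 of 6. Of 48 calls 43 were up (1532 genes with an unadjusted p under 0.05), and 32 were shared with AppNLGF minus WT. DESeq2 called 101, a fit of both groups alone 19, and the count was 29 without p16KO 11 or AppNLGF_p16KO 21 and 30 without p16KO 12. All 7 microglial genes and Gfap passed in the 12 fits without 1 library, and Gfap had adjusted p = 0.0596 with both groups alone (9.96e-06 to 0.0596 over its alternatives). The call of Il1r1 ended without p16KO 9, 10 or 12 or AppNLGF_p16KO 19, 20, 21 or 23 (adjusted p up to 0.132). That of Mns1 ended without any library except p16KO 8 and 12 and AppNLGF_p16KO 20 and 22 (up to 0.132), and that of Kdm7a except p16KO 7 and 9 and AppNLGF_p16KO 19, 22 and 23 (up to 0.132). That of Dnajb5 ended for all except AppNLGF_p16KO 22 and 23 (up to 0.132) and that of Rnf19a except p16KO 8 and 9 (up to 0.167). App was at log2 -0.06 ± 0.04 (adjusted p = 0.759), Cdkn2b at 0.33 ± 0.22 (adjusted p = 0.759) and Mtap at 0.20 ± 0.09 (adjusted p = 0.553). Near App, 1 of 96 genes within 10 Mb of App was called (odds ratio 4.32, Fisher's exact p = 0.212).

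Disease-associated microglia genes were again higher (median log2 0.33, 34 of 36 positive, camera adjusted p = 7.12e-36, adjusted p = 7.67e-05 with an estimated correlation, 12 called and 16 adjusted over the list alone). So were homeostatic microglia genes (median log2 0.18, camera adjusted p = 6.23e-10, adjusted p = 0.00685 with an estimated correlation, 2 called and 9 adjusted over the list alone). Gpr84 was among those called (log2 0.97 ± 0.18, adjusted p = 0.0118, 6 of 6). These 2 of 18 list calls held with an estimated correlation. Among those that did not hold, E2F targets and proliferation genes were called upward. That call ended without p16KO 7 (camera adjusted p = 0.121), 8 (0.0780), 9 (0.0797) or 11 (0.115) or AppNLGF_p16KO 19 (0.243) or 23 (0.101). Cholesterol synthesis genes were higher (median log2 0.29, 21 of 22 positive, camera adjusted p = 9.80e-20, adjusted p = 0.0584 with an estimated correlation, 1 called and 19 adjusted over the list alone). All 19 dentate gyrus genes were lower (median log2 -0.22, camera adjusted p = 1.05e-14, adjusted p = 0.0534 with an estimated correlation). edgeR called 0 over all genes and 10 adjusted over the list alone. The abundant members Ahcyl2 (log2 -0.18 ± 0.06, adjusted p = 0.369) and Zbtb20 (log2 -0.25 ± 0.18, adjusted p = 0.777) did not pass. In the same contrast interneuron genes (24 genes, median log2 0.05, camera adjusted p = 0.00988, adjusted p = 0.0618 with an estimated correlation) and oligodendrocyte and myelin genes (23 genes, median log2 0.11, camera adjusted p = 0.0138, adjusted p = 0.675 with an estimated correlation) were higher. edgeR called 0 members of both over all genes and over the list alone. AppNLGF_p16KO 21 had the lowest mean of all libraries for dentate gyrus genes (5.24) and the highest for oligodendrocyte genes (6.96). The oligodendrocyte call ended without p16KO 7 (0.256), 8 (0.0603) or 11 (0.0684) or AppNLGF_p16KO 21 (0.902, median 0.02) or 23 (0.133). The interneuron call ended without AppNLGF_p16KO 23 (0.0694), and its median was 0.08 without p16KO 8, 0.03 without p16KO 9 and 0.07 without AppNLGF_p16KO 18. Lysosomal genes were higher (median log2 0.12, camera adjusted p = 4.50e-13, adjusted p = 0.0618 with an estimated correlation, 3 called and 7 adjusted over the list alone). Among those called were Ctss (log2 0.44 ± 0.08, adjusted p = 0.0107) and Gusb (log2 0.28 ± 0.06, adjusted p = 0.0380). Complement genes were higher too (median log2 0.10, camera adjusted p = 1.05e-04, adjusted p = 0.159 with an estimated correlation, 3 called and 5 adjusted over the list alone). Those called were C3ar1 (log2 0.81 ± 0.15, adjusted p = 0.00736), C1qb (log2 0.49 ± 0.10, adjusted p = 0.0375) and C1qc (log2 0.47 ± 0.10, adjusted p = 0.0375), each higher in 6 of 6. Immediate early genes were lower (median log2 -0.13, camera adjusted p = 1.05e-04, adjusted p = 0.194 with an estimated correlation, 0 called by edgeR and 4 adjusted over the list alone). Their median was -0.06 without p16KO 9 and -0.05 without AppNLGF_p16KO 23. The glucocorticoid response list was called downward as well and did not hold with an estimated correlation (median log2 -0.12 without p16KO 7). The complement median was 0.24 without p16KO 7, 0.05 without p16KO 8 or 10, 0.16 without p16KO 11 and 0.15 without AppNLGF_p16KO 18 or 22. In the reactive astrocyte list the median (0.08) and the test pointed up and the mean (-0.04) down (camera adjusted p = 0.0400, adjusted p = 0.398 with an estimated correlation, 1 called, and 3 up and 2 down adjusted over the list alone). This last call was lost in 9 of 12 fits without 1 library, all except those without p16KO 7 and 9 and AppNLGF_p16KO 22 (adjusted p up to 0.128). The calls of C1qb and C1qc ended without p16KO 8, 10, 11 or 12 or AppNLGF_p16KO 18, 21 or 22 (adjusted p up to 0.132). That of Gusb ended without any library except p16KO 8 and AppNLGF_p16KO 19, 22 and 23 (up to 0.132). Without AppNLGF_p16KO 21 and 22 together, Gpr84 had adjusted p = 0.0736, C3ar1 0.0849 and Ctss 0.131, the highest of their alternatives (lowest 4.44e-04, 2.41e-05 and 4.30e-04).

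Whether the effects depended on each other was tested by the interaction. edgeR called 0 of 19423 genes (1021 with an unadjusted p under 0.05, smallest adjusted p = 0.897). The genes with the smallest p were the complement receptor gene C5ar2 (log2 -0.95 ± 0.22) and Bnip5 (log2 0.62 ± 0.15), neither past the threshold. DESeq2 called 1, the pseudogene Gm18733, chosen after its values were seen, with reads in 0, 2, 1 and 5 libraries of WT, p16KO, AppNLGF and AppNLGF_p16KO. The 62 genes called for AppNLGF minus WT had the same sign in AppNLGF_p16KO minus p16KO in 60 cases, 52 of them with an unadjusted p under 0.05. Across all genes the App effects of the backgrounds, which share no library, correlated weakly (Pearson r = 0.196, jackknife SE over libraries 0.119, Spearman rho = 0.0853, 53.5% of the same sign). The p16 effects correlated at r = 0.357 (jackknife SE 0.124, rho = 0.402, 67.8% of the same sign), and 59 of the 60 genes called for p16KO minus WT kept their sign with the knock-in, 43 with an unadjusted p under 0.05. The difference between these correlations was not tested. Genes are not independent replicates, so the correlations carry no p-value. Among lists, camera called 9 in the interaction and 0 held with an estimated correlation. Cholesterol synthesis genes had the smallest p (median log2 0.26, camera adjusted p = 1.58e-09, adjusted p = 0.433 with an estimated correlation), followed by dentate gyrus genes (median log2 -0.26, camera adjusted p = 1.43e-08, adjusted p = 0.433 with an estimated correlation, 0 of 19 positive). edgeR called 0 members of either over all genes, and 0 and 1 adjusted over the list alone.

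**Figure D4:**
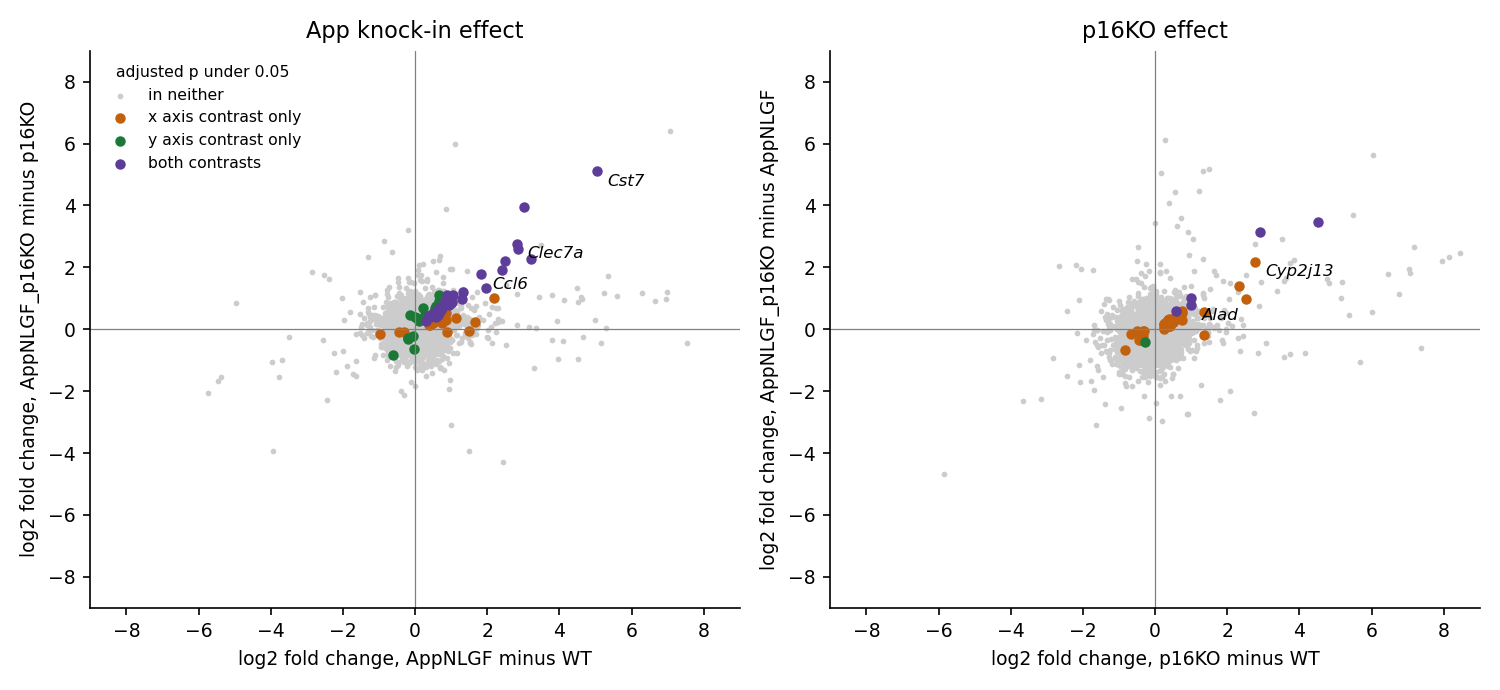
Log2 fold changes of all genes tested, on the left AppNLGF minus WT (x) against AppNLGF_p16KO minus p16KO (y) and on the right p16KO minus WT (x) against AppNLGF_p16KO minus AppNLGF (y), coloured by the contrast in which the adjusted p was under 0.05. On the left 32 genes were called in both contrasts and on the right 5.

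Averaged over both p16 backgrounds, the App knock-in raised Cst7 by log2 5.08 ± 0.24 (adjusted p = 1.25e-12) and Clec7a by 2.80 ± 0.17 (adjusted p = 4.05e-11). It raised Ccl6 by 1.81 ± 0.11 (adjusted p = 8.49e-11), Tyrobp by 0.95 ± 0.06 (adjusted p = 1.23e-10) and Itgax by 2.71 ± 0.18 (adjusted p = 1.23e-10), each in all 11 libraries with the knock-in by the separate contrasts. It called 154 genes, 126 up and 28 down (2018 with an unadjusted p under 0.05, 285 called by DESeq2). List calls that held with an estimated correlation were 5 of 21. They were disease-associated microglia (median log2 0.43, adjusted p = 6.22e-06 with an estimated correlation, 16 called and 22 adjusted over the list alone) and, in the same order of values, homeostatic microglia (0.20, 1.46e-04, 7 and 13), lysosome (0.12, 0.0252, 6 and 13), complement (0.20, 0.0112, 7 and 7) and, downward, immediate early genes (-0.20, 0.00514, 3 and 13). Without AppNLGF_p16KO 22 the median of homeostatic microglia genes was 0.13. The circadian clock and glucocorticoid response lists were also called downward and did not hold. Their calls ended without AppNLGF 14 (camera adjusted p = 0.0548) and without p16KO 7 (0.0778), respectively. Handling order cannot be told apart from the knock-in here either. The senescence and secretory phenotype list was called (median log2 0.05, camera adjusted p = 0.00946, adjusted p = 0.171 with an estimated correlation), with 1 of 41 genes called and 2 adjusted over the list alone. E2F targets and proliferation genes were called upward too and did not hold. That call ended without WT 3 (camera adjusted p = 0.0620) or AppNLGF_p16KO 19 (0.0749).

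Averaged over both App backgrounds, the libraries labelled p16KO or AppNLGF_p16KO were higher in Alad (log2 0.89 ± 0.08, adjusted p = 2.41e-06), Hdhd3 (1.01 ± 0.10, adjusted p = 2.56e-06), Tusc1 (0.58 ± 0.07, adjusted p = 2.95e-05) and Cyp2j13 (2.48 ± 0.34, adjusted p = 3.13e-04) and lower in Frrs1l (-0.38 ± 0.06, adjusted p = 0.00112). Changes were many and small. In all, 2522 genes passed, 1488 up and 1034 down (6025 with an unadjusted p under 0.05), with a median absolute log2 change of 0.21. Of these, 71 changed by at least 1 log2 unit. Of the nuclear oxidative phosphorylation genes 38 of 48 rose (median log2 0.19, camera adjusted p = 1.94e-21, adjusted p = 0.690 with an estimated correlation, 41 adjusted over the list alone). The 7 mitochondrially encoded genes were lower (median log2 -0.19, camera adjusted p = 0.00733, adjusted p = 0.787 with an estimated correlation, 3 called and 6 adjusted over the list alone). Of the cytosolic ribosomal protein genes 31 of 76 rose (median log2 0.15, camera adjusted p = 5.70e-12, adjusted p = 0.690 with an estimated correlation, 36 adjusted over the list alone), and of the interferon genes 16 of 31 fell (median log2 -0.50, camera adjusted p = 9.40e-10, adjusted p = 0.765 with an estimated correlation, 21 adjusted over the list alone). Targets of p53 were higher (median log2 0.11, 22 of 24 positive, camera adjusted p = 0.00733, adjusted p = 0.690 with an estimated correlation, 2 called over all genes and over the list alone). The cyclin-dependent kinase and Rb family (median log2 0.04, adjusted p = 0.416), E2F targets (0.05, adjusted p = 0.836) and the senescence and secretory phenotype (0.05, adjusted p = 0.478) were not called as lists, with 3, 3 and 5 members called over all genes. These member counts stand beside 2522 calls among all 19423 genes tested and were not compared with that share. With an estimated correlation 0 of the 9 list calls held. The count of genes was 925 without AppNLGF 16, 1174 without WT 5, 1342 without p16KO 9 or AppNLGF 17, 1403 without AppNLGF_p16KO 21. It was 1516 without WT 4, 1595 without p16KO 12, 1622 without WT 2, 1648 without AppNLGF_p16KO 20 and 5112 without AppNLGF_p16KO 23, and 1364 without a count filter. Within 10 Mb of Cdkn2a 21 of 70 genes were called (odds ratio 2.89, 1.64 to 4.92, Fisher's exact p = 2.04e-04). Genes up in both averages numbered 6, where 9.65 would be shared by independent lists, and those down in both 0 by edgeR, against 1.49.

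The last contrast set both changes together against WT. In libraries labelled AppNLGF_p16KO Cst7 (log2 4.70 ± 0.33, adjusted p = 6.84e-09), Tyrobp (1.10 ± 0.09, adjusted p = 1.56e-08), Trem2 (1.07 ± 0.09, adjusted p = 2.02e-08), Clec7a (2.81 ± 0.23, adjusted p = 3.13e-08) and Ccl6 (1.88 ± 0.16, adjusted p = 3.32e-08) rose in 6 of 6. The contrast called 1857 of 19423 genes, 1185 up and 672 down (5403 with an unadjusted p under 0.05), with a median absolute log2 change of 0.30. The member counts below were not compared with that share. Disease-associated microglia (21 of 36 called, 24 adjusted over the list alone, adjusted p = 0.00217 with an estimated correlation) and homeostatic microglia genes (8 of 23, 13 adjusted over the list alone, adjusted p = 0.0253 with an estimated correlation) were the 2 of 14 list calls that held. The senescence and secretory phenotype list was called (median log2 0.13, camera adjusted p = 0.0444, adjusted p = 0.311 with an estimated correlation, 3 of 41 called over all genes and over the list alone) and was lost without WT 2 (0.0547), WT 5 (0.105), AppNLGF_p16KO 21 (0.0732) or AppNLGF_p16KO 23 (0.0668). It was also lost with 15 reads in 90% of libraries (0.111), without both libraries 21 and 22 (0.0845) and without the chromosome of Cdkn2a (0.0710). The count of genes was 456 without AppNLGF_p16KO 21, 548 without WT 5, 822 without WT 4, 874 without WT 2. It was 1105 without AppNLGF_p16KO 20, 1150 without AppNLGF_p16KO 22, 2953 without WT 1 and 4448 without AppNLGF_p16KO 23, and 664 in a fit of both groups alone.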

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

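The tests of strain variants near the locus, of length and GC content for the chromosome and of a swap were set out before their results were seen. All other tests of this part, including every split of the samples, were chosen only after the result was seen. A library was marked when its gap to the next library was large against the range of its group by Dixon's test. Chance marks about 1 in 20 groups, and 13 of 204 group tests over 51 measures were marked.

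A first pattern was the gathering of p16 calls on chromosome 4. Genes within 10 Mb of Cdkn2a had odds ratios of 9.78 in p16KO minus WT (2 calls, 12.6 within 5 Mb with Fisher's exact p = 0.0802 and 11.2 within 20 Mb with p = 1.39e-04) and 55.91 in AppNLGF_p16KO minus AppNLGF (1 call, 1.243 with DESeq2 and 0 at an adjusted p under 0.01). With length and GC trends removed the odds ratio for the chromosome was 9.993 (lower bound 4.44), which argues against such a trend as the cause. Loss of p16 acting evenly on genes of any chromosome is argued against by the odds ratio of 7.168 for the chromosome. Its lower bound was 3.87, or 2.73 corrected for the choice among 22 chromosomes. The lower bounds were 0.302 within 5 Mb, 1.13 within 10 Mb and 3.45 within 20 Mb. The bound for the chromosome was asked for after the values were seen, and that within 10 Mb left this cause open. Fisher's test treats neighbouring genes as independent, and the 42 calls on other chromosomes are not addressed by it. Strain variants linked to the edited locus are a candidate explanation that the values of p16KO minus WT within 10 Mb fit, and Alad and Hdhd3 lie in a segment whose copy number varies between inbred strains, but no genotype was measured here.

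A second pattern was the library labelled AppNLGF_p16KO 22, marked for Cyp2j13 (0.03741 CPM, others of its group 0.3366 to 0.468) and Frrs1l (504.6 CPM, others 361.3 to 409.7). Its median position at the 18 called genes of chromosome 4 was 0.206, on a scale from 0 for the mean of AppNLGF to 1 for a full change of p16KO minus WT. Other libraries of its group lay at 0.448 (AppNLGF_p16KO 23) to 0.971. A swap with a library labelled AppNLGF is argued against, since the highest of those stood at 0.247 and none was out of place. A mouse without the linked segment on both chromosomes may account for the value. A wrong label cannot be told apart from a right one. The position of AppNLGF_p16KO 22 at the 42 called genes elsewhere was 0.74, where others of its group ranged from 0.145 to 1.05. The lowest, AppNLGF_p16KO 23, lay below AppNLGF 14 (0.299) and 15 (0.377) there. Against the 0.74, AppNLGF_p16KO 22 lay below the others of its group at scarce called genes off chromosome 4, chosen after their values were seen. These were Gm13453 (0.0748 CPM, others 0.326 to 1.3) and Gm20075 (0.168, others 0.919 to 1.999). A missing segment of chromosome 4 would not hold them. AppNLGF_p16KO 22 also held the most Cdkn2a reads of its group, 8.

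A last pattern was the 2522 small changes of the average p16 effect. With length and GC trends removed 2903 genes were called, 1795 of them shared. For those 1795 this argues against that trend as the whole cause. The other calls were lost, so a part of the trend in them is left open, and the total alone decides nothing. Across 14721 genes, which are not independent replicates, the effect correlated at 0.38 with the main axis of differences among libraries of the same genotype (20.2% of the residual variance), so that axis is a candidate explanation of part of the changes. The axis mostly followed sex (11 of 11 Xist libraries below 0, 11 of 12 others above, 63.5% of its variance). With the sex score in the model 2988 genes were called, 2517 of them shared. That count could hardly have fallen, since Xist marked 3 of 6, 3 of 6, 2 of 5 and 3 of 6 libraries. This near balance between genotypes, not the count, argues against sex as the cause. The main axis with sex removed correlated at 0.367. An effect of p16 loss cannot be told apart from handling order, since library numbers ran by genotype. Nor can it be told apart from other differences carried by mice of these labels, since no genotype was measured here. Of 42 calls on other chromosomes 97.62% kept their sign with the knock-in. Any difference shared by both groups labelled as lacking p16 would also give this.

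The real grouping was compared with 99 other splits of the same samples. For p16KO minus WT 1 of 100 splits, the real one, reached its 60 calls (highest other 3), and for AppNLGF minus WT 1 reached 62 (highest other 1). For the average App effect 1 reached 154 (highest other 2), for AppNLGF_p16KO minus WT 1 reached 1857 (highest other 6), and for the average p16 effect 1 reached 2522 (highest other 492). For AppNLGF_p16KO minus p16KO 2 splits reached 48 (highest other 422), and for AppNLGF_p16KO minus AppNLGF 3 reached 6 (highest other 3821). The share was under 0.05 for each of these, each taken alone without adjustment for the number of contrasts. Where only the real grouping reached its count, chance was argued against at that level. For AppNLGF_p16KO minus p16KO and AppNLGF_p16KO minus AppNLGF other splits reached the count, so chance was not excluded for those counts. The count of AppNLGF_p16KO minus AppNLGF also rests on few calls, since a fit of both groups alone called 0 by edgeR. For the interaction the real count was 0, which 100 of 100 splits reach by construction, so the splits decide nothing there (highest other 1788). In the split that called 3821 genes the share of Xist libraries differed by 0.267 between the compared groups, which was also the median of all splits. In the split that called 1788 the same contrast of shares was 0.8, as large in 14 of 99. Sex was therefore not shown to be the cause of these counts, which was not found. The surrogate variable of sva did separate the sexes (0.203 to 0.223 in Xist libraries and -0.226 to -0.157 in the others).

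Other libraries stood apart in single values. Total counts of AppNLGF 17 were 40.69 in units of 1e6 reads, against 52.29 to 56.97 in its group. AppNLGF 16 was low in C1qa (52.68 CPM, others 64.97 to 69.8), C1qb (50.51, others 64.58 to 67.71) and C1qc (48.17, others 59.99 to 63.83). WT 1 was high in Egr2 (5.698 CPM, others 2.742 to 3.771) and low in Gfap (273.4, others 330.3 to 363.7). WT 6 was high in Cdkn2b (0.8154 CPM, others 0.4575 to 0.5232). In p16KO, library 7 was high in Cd33 (13.61 CPM, others 9.758 to 11.04) and Il1r1 (40.3, others 19.05 to 24.8). Library 9 was high in Gpr84 (0.8843, others 0.5359 to 0.6359) and library 10 in Cd2ap (26.85, others 24.2 to 25.15).

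Gene lists were marked where the App effect differed between p16 backgrounds by the interaction test, and 0 of these 9 held with an estimated correlation. Median interactions (log2) were 0.257 for cholesterol synthesis, -0.256 for dentate gyrus, -0.903 for choroid plexus and ependyma and 0.134 for immediate early genes. They were 0.0908 for nuclear-encoded oxidative phosphorylation, 0.433 for meninges and fibroblasts and -0.197 for complement. The glucocorticoid response stood at -0.225 and CA1 at 0.164. Calls ended for oxidative phosphorylation without p16KO 7 (0.0745), AppNLGF 16 (0.101) or AppNLGF_p16KO 21 (0.136), with a median of 0.05 without AppNLGF 16, 0.04 without AppNLGF_p16KO 21 and 0.14 without AppNLGF_p16KO 23. They ended for meninges without p16KO 7 (0.0745) or AppNLGF 13 (0.118) or 14 (0.126), and for complement without WT 5 (0.0604) or p16KO 7 (0.0945, median -0.08). The glucocorticoid call ended without WT 5 (0.147), p16KO 7 (0.204, median -0.13), AppNLGF 16 (0.214, median -0.04) or AppNLGF_p16KO 23 (0.0537). The CA1 call ended without WT 2 (0.110), WT 6 (0.0507), p16KO 7 (0.0745), p16KO 9 (0.0993), AppNLGF_p16KO 22 (0.0834) or AppNLGF_p16KO 23 (0.0696). The choroid plexus median was -0.51 without p16KO 12.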

How the results depend on the processing

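The tests chosen only after the data were seen were the filter that returned 18768 genes, the omission of AppNLGF_p16KO 21 and 22, the removal of length and GC trends and the omission of the chromosome of Cdkn2a. No paired analysis was possible because the groups share no replicate numbers. Where no cause is named below, the cause was not tested. At an adjusted p under 0.01 the calls were 6 for p16KO minus WT, 3 for AppNLGF_p16KO minus AppNLGF, 22 for AppNLGF_p16KO minus p16KO, 233 for AppNLGF_p16KO minus WT, 167 for the average p16 effect and 89 for the average App effect. The odds ratio near Cdkn2a in AppNLGF_p16KO minus AppNLGF was then 0, since 0 of the 3 genes left by edgeR lay there. A log2 change of at least 0.5 left 18 in p16KO minus WT, 335 in AppNLGF_p16KO minus WT, 255 in the average p16 effect and 66 in the average App effect. DESeq2 called 469 in p16KO minus WT, 153 in AppNLGF minus WT, 676 in AppNLGF_p16KO minus AppNLGF and 101 in AppNLGF_p16KO minus p16KO. It called 1 in the interaction and 285 in the average App effect, and its odds ratio near Cdkn2a in AppNLGF_p16KO minus AppNLGF was 1.243. With the compared groups alone the calls were 307 in p16KO minus WT, 0 by edgeR in AppNLGF_p16KO minus AppNLGF, 19 in AppNLGF_p16KO minus p16KO and 664 in AppNLGF_p16KO minus WT.

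Without AppNLGF_p16KO 21, past the submitters' distance limit, the calls were 181 in p16KO minus WT, 29 in AppNLGF_p16KO minus p16KO, 456 in AppNLGF_p16KO minus WT and 1403 in the average p16 effect, with 15 lists in the interaction. Without 21 and 22 they were 210, 18, 144 and 461. The ribosomal list in AppNLGF_p16KO minus p16KO turned to a median of 0.01174 with the test downward, and App in AppNLGF_p16KO minus AppNLGF to 0.00825. Removing length and GC trends left 32 calls in p16KO minus WT and turned App in p16KO minus WT to 0.026, Mtap in AppNLGF minus WT to 0.02644 and App in AppNLGF_p16KO minus AppNLGF to 0.05975. Without the chromosome of Cdkn2a 38 calls were left in p16KO minus WT and 2 in AppNLGF_p16KO minus AppNLGF. Of the calls with that chromosome, 18 of 60 and 3 of 6 lay on it, and the cause of the other losses was not tested. With 15 reads in 90% of libraries AppNLGF_p16KO minus AppNLGF had 3 calls, and Mtap in AppNLGF minus WT turned to 0.003052. With no count filter the calls were 17 in AppNLGF_p16KO minus AppNLGF, 1072 in AppNLGF_p16KO minus WT and 1364 in the average p16 effect, with 15 lists in AppNLGF_p16KO minus AppNLGF. The agreement across genes was then 0.07427 for p16 effects and 0.01519 for App effects. A window of 5 Mb gave an odds ratio of 12.6 in p16KO minus WT. With an estimated correlation the lists called were 0 in p16KO minus WT, 4 in AppNLGF minus WT, 0 in AppNLGF_p16KO minus AppNLGF, 2 in AppNLGF_p16KO minus p16KO, 2 in AppNLGF_p16KO minus WT, 0 in the interaction, 0 in the average p16 effect and 5 in the average App effect. With the preset correlation camera had called 10, 17, 9, 18, 14, 9, 9 and 21.

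Leaving out 1 library at a time, calls ran from 7 to 238 in p16KO minus WT, 2 to 4150 in AppNLGF_p16KO minus AppNLGF, 29 to 61 in AppNLGF_p16KO minus p16KO, 456 to 4448 in AppNLGF_p16KO minus WT and 925 to 5112 in the average p16 effect. They ran from 47 to 66 in AppNLGF minus WT, and from 4 to 15 for lists in the interaction. Mtap in AppNLGF minus WT ran from -0.03817 to 0.03555 and App in AppNLGF_p16KO minus AppNLGF from -0.02588 to 0.00871. Over these fits 1112 results for single genes kept their direction and side of the threshold, 204 were weaker, 6 stronger and 7 reversed, and for single lists 1554 kept theirs and 133 were weaker. Under the other settings 1281 results for single genes were kept, 79 weaker, 8 stronger and 5 reversed, and for lists 1216, 135 weaker and 1 reversed. Depth limits what can be said of Cdkn2a, at 0 to 9 reads per library.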

Other observations

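The hypothesis tests of this closing section are those given above, and the values here were chosen only after they were seen. Lists for tissue next to the hippocampus moved too. Choroid plexus and ependyma genes were higher in AppNLGF minus WT (24 genes, median log2 0.39, camera adjusted p = 4.98e-04, adjusted p = 0.593 with an estimated correlation). They were lower in AppNLGF_p16KO minus AppNLGF (median log2 -0.71, camera adjusted p = 0.00186, adjusted p = 0.846 with an estimated correlation). edgeR called 0 members in either contrast over all genes and over the list alone. The first call ended without WT 2 (adjusted p = 0.141, median 0.17), and its median was 0.66 without WT 3, 0.65 without WT 4, 0.21 without AppNLGF 15 and 0.24 without AppNLGF 16. The second call ended without AppNLGF_p16KO 19 (adjusted p = 0.0642). The choroid plexus marker Ttr, the transthyretin gene, ran from 78.62 CPM in WT 2 to 5395 CPM in p16KO 12. Other such lists were called in AppNLGF minus WT with 0 members called by edgeR over all genes or over the list alone. Meninges and fibroblast genes were lower (20 genes, median log2 -0.29, camera adjusted p = 0.00332, adjusted p = 0.553 with an estimated correlation). That call ended without AppNLGF 13 (0.0861) or 14 (0.124), and its median was -0.57 without AppNLGF 16. Striatum genes were higher (14 genes, median log2 0.15, camera adjusted p = 0.0114, adjusted p = 0.636 with an estimated correlation). That call ended without WT 5 (0.0622) or AppNLGF 15 (0.415, median -0.04), and its median was 0.52 without WT 1 and 0.24 without AppNLGF 16. Neocortex genes were lower (18 genes, median log2 -0.10, camera adjusted p = 0.0275, adjusted p = 0.409 with an estimated correlation). That call ended without WT 1 (0.0991) or 4 (0.0721) or AppNLGF 13 (0.0829) or 14 (0.126), and its median was -0.07 without WT 1.

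Neuronal and mitochondrially encoded lists were also called. Excitatory synapse genes were lower in AppNLGF_p16KO minus AppNLGF (29 genes, median log2 -0.11, camera adjusted p = 2.43e-04, adjusted p = 0.660 with an estimated correlation) and in AppNLGF_p16KO minus p16KO (median log2 -0.09, camera adjusted p = 5.80e-05, adjusted p = 0.360 with an estimated correlation). The latter median was -0.05 without AppNLGF_p16KO 18, -0.04 without 21 and -0.14 without 23. CA1 genes were lower in AppNLGF minus WT (14 genes, median log2 -0.11, camera adjusted p = 0.01, adjusted p = 0.199 with an estimated correlation). The 7 mitochondrially encoded genes were lower in p16KO minus WT (median log2 -0.13, camera adjusted p = 0.0238, adjusted p = 0.729 with an estimated correlation), opposite to the nuclear genes of oxidative phosphorylation. That call ended without WT 5 (0.122, median -0.07) or p16KO 9 (0.124, median -0.08). They were also lower in AppNLGF_p16KO minus AppNLGF (median log2 -0.15, camera adjusted p = 0.0171, adjusted p = 0.660 with an estimated correlation), a call that ended without AppNLGF 14 (0.0555). They were higher in AppNLGF minus WT (median log2 0.14, camera adjusted p = 0.0275, adjusted p = 0.533 with an estimated correlation). This call ended without WT 1 (0.0801), WT 2 (0.125), WT 4 (0.0935), AppNLGF 14 (0.0602) or AppNLGF 17 (0.0635). In the average App effect they were higher too (median log2 0.09, camera adjusted p = 0.00916, adjusted p = 0.389 with an estimated correlation), a call that ended without p16KO 9 (0.0614), with a median of 0.13 without WT 5. edgeR called 0 of the 7 over all genes in these 4 contrasts, and 1, 3, 0 and 1 adjusted over the list alone.

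Some libraries had further values apart from their group. At Gm13453, on chromosome 2, AppNLGF_p16KO 22 had 0.0748 CPM (others of its group 0.326 to 1.3, AppNLGF 0 to 0.122). At Gm20075, on chromosome 13, it had 0.168 CPM (others 0.919 to 1.999). It also held the most Cdkn2a reads of its group, 8. AppNLGF_p16KO 21 had 1251 Xist reads beside 8308 reads of Y-linked genes, where other libraries with Y-linked reads had 99 to 497. WT 6 and AppNLGF_p16KO 19 had 43 and 19 reads of Y-linked genes beside Xist, against 0 to 2 in the others. The mean of the interferon list was highest in AppNLGF 17 (2.26) and next in AppNLGF 16 (1.43).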
